A study of Cereibacter sphaeroides 2.4.1 with 6 samples.

How the data were processed

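Total RNA of 3 wild type and 3 PrrA2 mutant cultures was converted to cDNA, biotin-labelled and hybridised to 1 array each, per the labels' protocols. Cultures grew in the dark under a mixture of nitrogen and carbon dioxide, with 0.5% DMSO by volume and 0.1% yeast extract, to an OD600 near 0.4. Per the labels, the cultures were independent and grown in quadruplicate, and 3 were chosen afterwards. The basis of the choice is not given in the sources used here, so the p-values cover the spread between the chosen cultures only. The deposited values are linear MAS5 signals, an intensity per probe set computed by the authors, per the submitters' processing notes. The MAS5 version, its settings and the genome build of the array design are not given in the sources used here. The mean after trimming 2% from each end was 500.1 on all 6 arrays, so the values are scaled to a common target. Such a scaling sets the trimmed means equal and cannot show a change in total RNA per cell. No detection calls were used here, and 6.16% to 10.3% of the values per array lay under 20. The number of arrays limits the precision.

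The table held 5355 probe sets, of which 542 have a single gene symbol in the platform annotation, 0 have several and 4813 have none here. Unnamed probe sets may or may not stand for genes. The 3 thrC probe sets, which alone are named by a separate GenBank record, were taken as an added control RNA and left out of the tests. Neither its addition nor its amount is given in the sources used here, so scaling to it rests on an untested assumption of equal amounts. The other 539 named probe sets stand for 514 genes, and the probe set with the highest mean log2 signal stood for each of the 10 genes with several. Such probe sets lay at -1.66 to -1.35 for appA, -3.42 to -3.24 for bchF and -3.74 to -3.45 for pufA, with all 5 called for each. For fnrL they spanned -0.36 to 0.03 and for ppsR -0.14 to 0.40, with 1 of 5 called for each. A symbol shared by several genes is given with its probe set number.

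Log2 signals were fitted without further normalization in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. Fold changes come from differences of mean log2 signals, as mutant minus wild type, and means ± SD are of linear signals. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. With an estimated correlation camera takes its p from the 4 residual degrees of freedom here, which limits its power. List p-values were adjusted over the 17 lists tested. Lists with under 3 members had no set test, and the regulators were reported singly. Measured members of a list are those named here, and unnamed probe sets may stand for further members. Of 23 lists 21 had measured members in this sense. The lists of other terminal oxidases and of nitrate and nitrogen oxide reduction had 0. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

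The groups, tests, gene lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule takes prrA, prrB and prrC; the 12 largest rises and 12 largest falls among called genes whose groups do not overlap; up to 3 called members per list with the largest change, or the member with the smallest p; and every called regulator. Lists were filled by symbol only, because the annotation used here gives neither products nor locus tags. Gene neighbours and replicons came from the RefSeq annotation of assembly ASM332471v1, in which 447 of the 514 genes (87.0%) were matched by symbol. Its coordinates are not printed because the build of the array is not given. It gives no strand, so neighbouring pairs were taken regardless of strand. A level of prrA and a separate test of intergenic probe sets were planned and not run, since no probe set used here is named in that way.

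On simulated data made from the 514 named genes, with 200 changed, limma recovered 70.1% of changes of 0.5 (log2), 98.5% of changes of 1 and 100% of changes of 2, with 4 false calls (2.19% of calls). With 5352 probe sets, of which 200 were again changed, the recovered shares were 31.3%, 65.7% and 84.8%, with 5 false calls. The real fit called 2807 of them, so these shares do not describe it. A list shifted by 1 log2 unit was recovered in 100 of 100 simulations, with 12 calls among 1600 tests of unchanged lists. Genes varied independently and with the same spread in these list simulations. Real lists can move together, with an estimated correlation of 0.504 for the photosynthetic complexes and 0.976 for the cbb3 oxidase. The simulated rates do not carry over to such lists. Alternatives covered normalization, low values, the variance model, a replicate block, leaving out each array, the thresholds and the set test. Cyclic loess, quantile normalization over all probe sets, scaling to the thrC control, leaving out genes above a signal of 4000 and a camera background of all probe sets were added after seeing the data.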

Results

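RNA was measured in 6 cultures of the purple bacterium Rhodobacter sphaeroides 2.4.1, 3 of the wild type and 3 of a strain called the PrrA2 mutant. PrrA is the response regulator of the PrrBA sensor and regulator pair, which adjusts transcription to oxygen. The question was the role of this global regulator in dark, oxygen-free growth with DMSO, the electron acceptor for respiration. Median signals were 180 to 203.3 on the wild type arrays and 220.6 to 233.7 on the mutant arrays, and the 99th percentiles were 13161 to 16422 and 5243 to 7074. The bright end of the scale was lower on all 3 mutant arrays. Signals of the 3 thrC probe sets, taken here as an added control RNA, were 2.56-fold to 2.63-fold lower there. The sources used here do not state whether that RNA was added, or in equal amounts, so values scaled to it hold only if it was. Spearman correlations across probe sets, which are not independent replicates, were 0.964 to 0.976 within the wild type, 0.985 to 0.989 within the mutant and 0.846 to 0.873 between the groups.

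The mutant had far less RNA from the genes of the photosynthetic apparatus, and more from the pqq genes of pyrroloquinoline quinone synthesis, trxA for thioredoxin, and the DMSO respiration regulators dorS and dorR. Transcripts of pufL and pufM, which encode reaction centre subunits, fell 46.4-fold and 44.4-fold. The signal of pufL was 18194 ± 2752 in the wild type and 392 ± 59.5 in the mutant (SD, n = 3 each), and that of pufM was 17142 ± 2234 and 384 ± 14.2. The signal of trxA went from 322 ± 23.3 to 2399 ± 199, a 7.45-fold rise, and that of pqqD from 93.4 ± 23.6 to 765 ± 26.7, an 8.37-fold rise. Of 514 named genes, 198 rose and 144 fell by limma at an adjusted p under 0.05, 61 and 68 of them by at least 2-fold. The groups did not overlap for 363 genes (70.6%), where chance gives 10%. Rises made up 57.9% of these calls, but 35.3% after centring each array on its median, 42.1% after cyclic loess, 86.2% after centring on ribosomal protein genes and 94.1% after scaling to the thrC control. The median named gene changed by 0.11 (log2), and list medians are therefore also given relative to the other named genes. Ribosomal centring adds 0.85 and control scaling 1.39 to every change, so that falls smaller than this turn. Control scaling also moves each array by its own thrC signal. The mean of that signal was 21789 to 31578 on the wild type arrays and 7883 to 14133 on the mutant arrays. A call lost under control scaling can therefore come from added spread within the groups as well as from the shift.

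**Figure D1:**
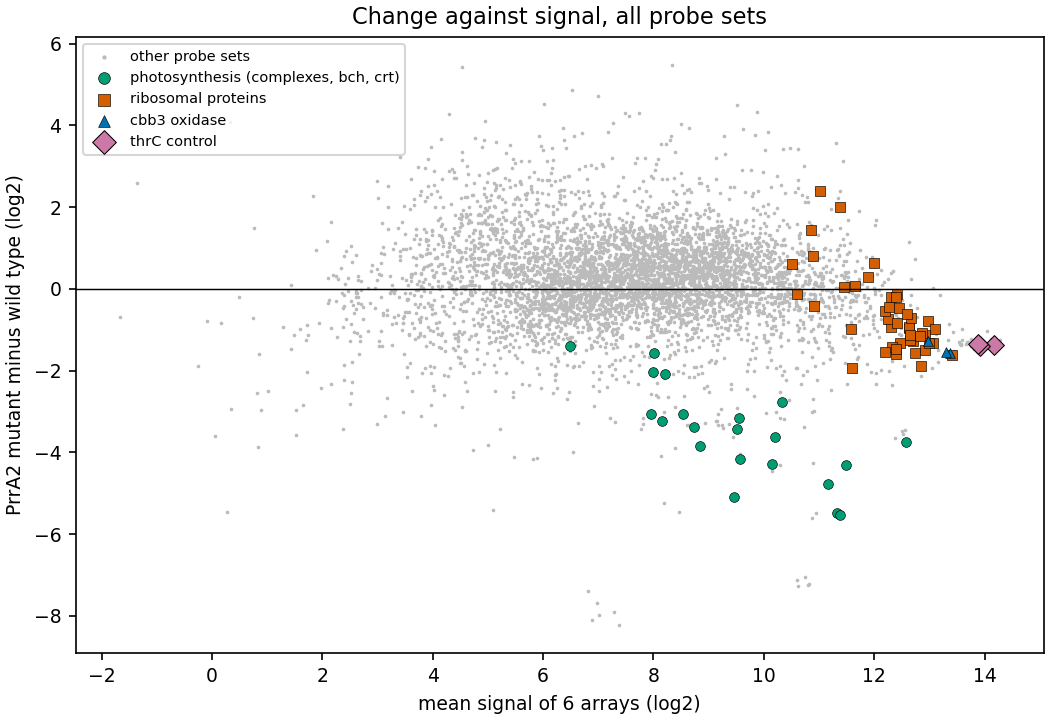
Log2 change (mutant minus wild type) of each probe set against its mean log2 signal on the 6 arrays, with photosynthesis genes, ribosomal protein genes, cbb3 oxidase genes and the thrC control marked. All 21 photosynthesis genes lie below 0, with some other probe sets lower still at like signal, while the control probe sets at the bright end lie near -1.36.

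All 6 measured genes of the photosynthetic complexes fell, with a median log2 change of -4.93 (-5.06 relative to the other genes). Besides pufL and pufM, pufQ fell 34.1-fold, pufX 27.3-fold, puhA for the reaction centre H subunit 19.8-fold and pufA for a light-harvesting polypeptide 13.4-fold. All 11 bacteriochlorophyll synthesis genes fell (median -3.24, or -3.38 relative to the other genes), led by bchL at 17.8-fold, bchZ at 14.3-fold, bchE at 12.3-fold and bchF at 10.7-fold. All 4 carotenoid genes fell (median -2.06, or -2.18 relative to the other genes), crtA by 19.4-fold, crtB by 4.26-fold and crtC by 4.07-fold. Every one of these 21 genes also fell after median centring, quantile normalization and cyclic loess, 20 fell after centring on ribosomal protein genes, and 17 fell after scaling to the thrC control. The losses under control scaling were 3 of the 4 carotenoid genes, crtB (adjusted p = 0.0829) and crtC (0.121) among them, and 1 bacteriochlorophyll gene. The carotenoid median was then -0.67, and -1.21 after ribosomal centring. The set test camera gave adjusted p = 2.2e-07 for the complexes, 1.91e-09 for bacteriochlorophyll and 0.00169 for carotenoids. With an estimated correlation the adjusted p was 0.205, 0.0393 and 0.19, so that only the bacteriochlorophyll call held. The estimates were 0.504, -0.0112 and -0.182, below the preset 0.01 for the last 2 lists. The higher p of those lists therefore does not come from a higher correlation.

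**Figure D2:**
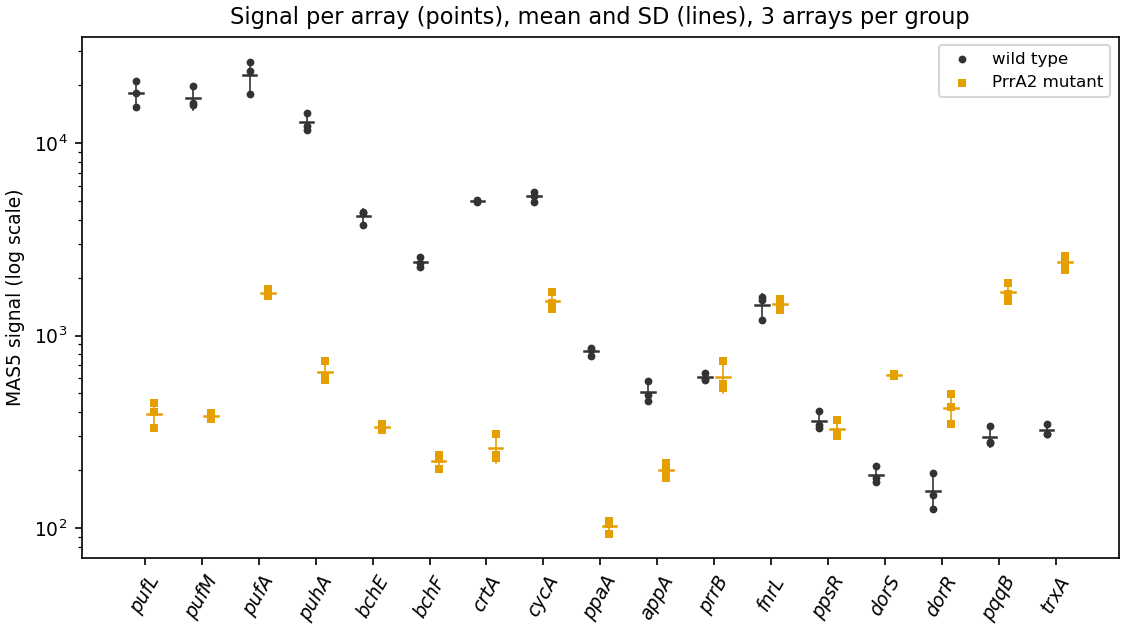
MAS5 signal on a log axis for 17 genes, with points for the arrays and lines for the mean and SD of 3 arrays per group. The signals of pufL, pufM, puhA, bchE and crtA do not overlap between the groups, while those of prrB and fnrL do.

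Among 16 measured regulators of photosynthesis and redox responses, 7 rose, 4 fell and 5 did not pass the test. The largest fall was in ppaA, from 827 ± 38.8 to 102.5 ± 8.39 (8.08-fold, n = 3), followed by tspO (3.73-fold, not called after control scaling), appA for a light and redox sensing antirepressor (2.54-fold) and ihfB (1.62-fold). After scaling to the thrC control the change of appA was 0.04 and that of ihfB 0.69 (log2), and that of ihfB was 0.15 after centring on ribosomal protein genes. The genes dorS and dorR rose 3.32-fold and 2.72-fold. These 2 are the only named genes of the DMSO respiration list, so the level of the DMSO reductase genes is not known here. Rises were smaller for rpoE (2.26-fold), rpoZ (1.95-fold), chrR (1.91-fold), cbbR (1.75-fold) and ihfA (1.25-fold). The call of ihfA was lost without wild type replicate 3 (adjusted p = 0.0934), after median centring (0.826) and without an intensity trend (0.0524). The sensor kinase gene prrB had a signal of 607 ± 29.9 in the wild type and 610 ± 108 in the mutant, with a log2 change of -0.01 (SE 0.13, adjusted p = 0.971). This became -0.36 after cyclic loess (adjusted p = 0.0458), 0.85 after ribosomal centring and 1.38 after control scaling. Of the other regulators that did not pass, chosen here after their values were seen, fnrL had a log2 change of 0.03, ppsR -0.14 and rpoD -0.01. The symbols prrA and prrC are not among the names used here, so no probe set named for the mutated gene could check the labels. The unnamed probe sets 2420 and 2424, which had the largest falls of all probe sets, lie close to prrB (probe set 2426) in the numbering. Whether either of them measures prrA is not given in the sources used here.

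In electron transport, all 3 measured subunit genes of the cbb3 oxidase, the high-affinity terminal oxidase, fell: ccoO 2.95-fold, ccoN 2.91-fold and ccoP 2.41-fold. These are among the brightest genes, and none of the 3 fell after either quantile normalization or after scaling to the thrC control, where ccoP changed by 0.12, and ccoO changed by 0.03 after quantile normalization over the named genes. The list passed camera (adjusted p = 0.0445) but not with an estimated correlation (adjusted p = 0.577), nor without wild type replicate 1 (0.0566), 2 (0.068) or 3 (0.0574) or mutant replicate 3 (0.0736). The cytochrome c2 gene cycA fell 3.5-fold, while its change after control scaling was -0.42 (adjusted p = 0.181). In its list of 4 genes, 2 rose and 2 fell (camera adjusted p = 0.653), and the calls of ccmB (1.41-fold lower) and ccmD (1.3-fold higher) were lost without wild type replicate 2 (adjusted p = 0.074 and 0.0617), mutant replicate 2 (0.0506 and 0.0638) or mutant replicate 3 (0.0683 and 0.108), or with a floor at the 10th percentile (0.0527 and 0.0602). The call of ccmD was also lost after median centring, cyclic loess and either quantile normalization, and the change of ccmB was 0.36 after ribosomal centring and 0.90 after control scaling.

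Of 9 NADH dehydrogenase genes 5 rose, 1 fell and 3 did not pass (median 0.28, or -0.01 after median centring, adjusted p = 0.38), with nuoF up 2.16-fold, nuoE 1.8-fold and nuoN 1.51-fold. Of 4 ATP synthase genes 3 fell (median -0.68, adjusted p = 0.177), but 0 after ribosomal centring (median 0.17) or control scaling (0.70). They were atpA (probe set 3231, 1.85-fold) and 2 genes named atpD (probe set 3233, 1.63-fold, and probe set 4901, 1.58-fold). Their direction turned after control scaling for all 3, after ribosomal centring for both atpD genes, and after quantile normalization over the named genes for atpA and atpD (probe set 3233), the latter also after cyclic loess and quantile normalization over all probe sets. The change of atpA (probe set 3231) was -0.19 after cyclic loess (adjusted p = 0.0704), -0.11 after quantile normalization over all probe sets (0.334) and -0.03 after ribosomal centring (0.724). Of 8 genes of the TCA cycle 5 fell (median -0.48, adjusted p = 0.177), but 2 after quantile normalization over the named genes or cyclic loess and 0 after ribosomal centring (median 0.37) or control scaling (0.91). They include gltA for citrate synthase (1.96-fold) and sucC (1.67-fold), which both lay above the wild type after control scaling, and sucC also after ribosomal centring, where the call of gltA ended. The change of sucC was -0.08 after quantile normalization over the named genes (adjusted p = 0.464) and -0.21 after cyclic loess (0.0609). The fall of fumC (probe set 4995, 2.12-fold), which turned after control scaling, was lost without wild type replicate 2 (adjusted p = 0.141) or 3 (0.0645), or without mutant replicate 1 (0.0506), 2 (0.0584) or 3 (0.201). It was also lost with the replicate block (0.0529), in a fit of all probe sets (0.0658), without genes above 4000 (0.0502), after ribosomal centring (-0.23, 0.649) and with a floor at the 10th percentile, where its change was -0.06 (0.389). Without single arrays 3 or 4 of the 8 TCA cycle genes fell, and 3 fell with the replicate block.

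Of 45 ribosomal protein genes 32 fell, 7 rose and 6 did not pass (median -0.92, or -1.11 relative to the other genes, camera adjusted p = 1.2e-05, and adjusted p = 0.577 with an estimated correlation). After quantile normalization over the named genes 12 fell and 18 rose, after the same over all probe sets 16 fell and 16 rose, after cyclic loess 24 fell and 11 rose, and after control scaling 1 fell and 23 rose. The gene rpmI fell 3.85-fold, with a log2 change of -0.56 after control scaling (adjusted p = 0.0657), while rpmH and rpsT rose 5.27-fold and 4.04-fold. The gene rnpA, for the protein part of RNase P, rose 5.1-fold.

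Of 8 genes for haem and its precursors 4 fell and 1 rose (median -0.22, adjusted p = 0.38). The first enzyme gene, hemA, went from 9442 ± 949 to 2781 ± 40.4 (3.38-fold lower, n = 3), with a change of -0.37 after control scaling (adjusted p = 0.142). The coproporphyrinogen oxidase genes moved apart, hemN falling 2.25-fold (0.22 in log2 after control scaling) and hemF rising 2.86-fold. Of 11 cobalamin genes 4 rose and 2 fell (adjusted p = 0.676), with cobD up 2.16-fold, cobJ up 1.52-fold and cobO down 1.53-fold, the last at 0.24 after ribosomal centring and 0.77 after control scaling. The call of cobJ was lost without mutant replicate 3 (adjusted p = 0.0594), and after median centring, cyclic loess or either quantile normalization.

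Of 7 genes for iron uptake and iron-sulphur clusters 3 rose and 3 fell, with a median of -0.12 but an upward camera test (adjusted p = 0.754). The rises were exbD (4.24-fold), exbB (2.88-fold), both parts of an energy-transducing complex for outer membrane transport, and bfr for bacterioferritin (probe set 2452, 2.63-fold). The falls were the other bfr gene (probe set 4296, 2.16-fold), sufB (1.84-fold) and sufC (log2 change of -0.29). Of 20 genes for flagella and chemotaxis 7 fell and 13 did not pass (median -0.66, but 0.19 after ribosomal centring and 0.73 after control scaling, adjusted p = 0.146), with flgG, a rod gene, down from a signal of 124 ± 33.1 to 8.87 ± 2.61, flgB down 3.34-fold and motA down 2.96-fold. The signal of flgG in the mutant lay under 20, in the low range, so no fold is given, and with a floor at the 10th percentile its change was -0.50 (adjusted p = 0.0663). With that floor the flagellar median was -0.02 and 3 genes fell, and leaving out the dimmest genes kept 1 of the 20, which did not fall. The calls of flgB and motA were lost after control scaling.

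Of 11 nitrogen fixation genes nifA, the activator, fell 5.24-fold, nifD rose and 9 did not pass (median 0.31 with a downward camera test, adjusted p = 0.928). The signal of nifD was 17.7 ± 2.06 and 48.2 ± 10.2, under 20 in the wild type, so no fold is given, with no difference left at a floor at the 10th percentile, and its call was lost without mutant replicate 1 (adjusted p = 0.0859) or 3 (0.142), and after median centring, cyclic loess or either quantile normalization. Of 5 hydrogenase genes 2 rose (adjusted p = 0.427), hypE by 2.21-fold and hypF by 1.43-fold, the latter not passing without wild type replicate 1 (adjusted p = 0.179) or 3 (0.109) or mutant replicate 2 (0.156) or 3 (0.143), with a floor (0.118), without a trend (0.0797), in a fit of all probe sets (0.0749) or without genes above 4000 (0.0514), nor after median centring, cyclic loess or either quantile normalization. Of the 2 measured genes of CO2 fixation cbbX fell 1.95-fold and cbbR rose, and cbbX lay 0.43 above the wild type after control scaling and was not called after ribosomal centring. Of 9 chaperone and protease genes 3 rose and 4 fell (adjusted p = 0.676), among them clpA (1.69-fold up), dnaJ (1.69-fold up) and groEL (probe set 4571, 2.25-fold down, but 0.22 after control scaling and not called after ribosomal centring). Of 4 uptake genes for organic solutes 1 fell, xylF by 1.4-fold (list adjusted p = 0.417), with a change of 0.37 after ribosomal centring and 0.91 after control scaling. The measured polyhydroxybutyrate gene phaC had a log2 change of 0.27 (adjusted p = 0.0903), but passed without wild type replicate 1 (0.37, adjusted p = 0.0382), after ribosomal centring (1.12, 3.71e-06) and after control scaling (1.66, 3.43e-05). Adjusted over the list alone, the counts differed from those over all genes for 4 lists, namely cobalamin (3 rose, 2 fell), nitrogen fixation (0 rose, 1 fell), hydrogenase (1 rose) and flagella (5 fell).

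**Figure D3:**
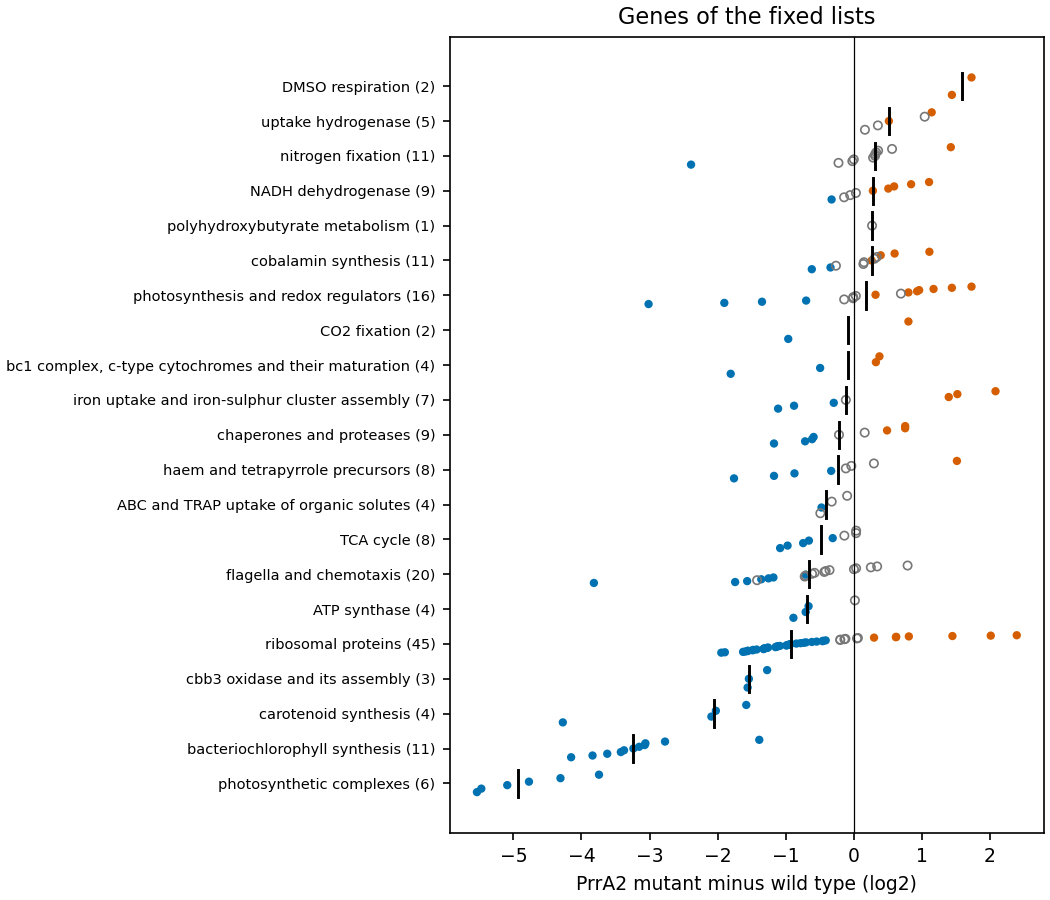
Log2 change (mutant minus wild type) of each member of the 21 lists with measured genes, with the number of members in brackets and the median as a black line; vertical offsets within a list only separate the points. Filled blue points fell, filled orange points rose and open points did not pass the test, and the 6 genes of the photosynthetic complexes all lie below -3.7.

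Other large rises among named genes were pqqB (5.61-fold), pqqE (4.98-fold) and dnaQ (5.08-fold). The last started from a dim and variable wild type signal of 69.8 ± 41.6 and reached 304 ± 39.9. Also called as rises were tdh (probe set 5010) and recF, from dim wild type signals of 21.1 ± 8.72 and 45.3 ± 33.3 to 119 ± 7.75 and 165 ± 20.5. The call of kdpA, with signals of 15.9 ± 8.69 and 58.7 ± 7.72, is given without a fold for its low wild type signal, and its change was 0 with a floor at the 10th percentile. Of 406 named genes matched to chromosome 1, 166 rose and 114 fell, and of 32 on chromosome 2, 8 rose and 6 fell, with medians of 0.15 and -0.12 (camera adjusted p = 0.946 for both). Of 142 pairs of neighbouring named genes 45.8% were called in the same direction, against 23.4% on average in 10000 shuffles of gene order (highest 37.3%, permutation p = 0.0001, one-sided, the smallest that these shuffles can give). Over all 5352 probe sets 1810 rose and 997 fell, and 4813 of them have no name here. Of the unnamed probe sets, number 2420 fell from 2879 ± 210 to 10.2 ± 4.18 and number 2424 from 2005 ± 400 to 7.27 ± 1.46 (n = 3 each), and no fold is given because the mutant signals lay under 20, in the low range. The largest rise was from 56.8 ± 32.6 to 2152 ± 98.1.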

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

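Cyclic loess, quantile normalization over all probe sets, scaling to the thrC control, leaving out genes above a signal of 4000 and the camera background of all probe sets were chosen after the data were seen. List values are medians relative to the other genes (log2), and the cause was not tested except where stated. Genes that rose numbered 117 after median centring, 375 after ribosomal centring, 130 after cyclic loess and 401 after control scaling, and genes that fell numbered 60, 25 and 84 after ribosomal centring, after control scaling and without genes above 4000. The last tested fewer genes. A 2-fold bound left 129 genes, 61 up and 68 down. Over all probe sets control scaling gave 4030 rises and 130 falls. Without single arrays the called genes numbered 297 to 348. The cbb3 list no longer passed after quantile normalization over the named genes (-0.16) or all probe sets (-0.20), median centring or control scaling (-1.66 each), a floor (-1.56), a pseudocount (-1.56), without the dimmest genes (-1.59), after cyclic loess (-0.52) or with an estimated correlation (-1.66). Without single arrays it lay at -1.83 to -1.53. Ribosomal proteins no longer passed after cyclic loess (-0.21), quantile normalization over all probe sets (-0.15), control scaling (-1.11) or an estimated correlation (-1.11), and the camera direction turned after quantile normalization over the named genes (-0.12) and without genes above 4000 (-0.22). With an estimated correlation the photosynthetic complexes (-5.06) and carotenoids (-2.18) also missed the threshold. Flagella passed after quantile normalization over the named genes (-0.78), after ribosomal centring, without a trend, after control scaling and against all probe sets (-0.80 each), and without genes above 4000 (-0.95). With a floor the flagellar value was -0.06 (adjusted p = 0.223), with a pseudocount -0.25 (adjusted p = 0.143), and without the dimmest genes 1 of 20 members was left, so that dim signals limit this list. NADH dehydrogenase passed after quantile normalization over the named genes (0.45) and cyclic loess (0.39). Against all probe sets ATP synthase (-0.81) and the TCA cycle (-0.62) passed. By fry, which tests whether a list's genes move on balance 1 way and not the relative medians given here in brackets, haem (-0.34), cytochrome c (-0.20), hydrogenase (0.43), flagella (-0.80), NADH dehydrogenase (0.17), ATP synthase (-0.81), TCA cycle (-0.62), chaperones (-0.33), iron (-0.23) and solute uptake (-0.52) passed, and for iron the direction of fry was up, against its median. By fry chromosome 2 moved up (adjusted p = 0.0439) while it lay -0.28 from chromosome 1, which also passed fry (adjusted p = 0.00151).

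Signs turned for these genes, given as log2 changes. After quantile normalization over the named genes ccoO was 0.034, atpA (probe set 3231) 0.021 and atpD (probe set 3233) 0.27, and the last was 0.0022 after cyclic loess and 0.12 after quantile normalization over all probe sets. After ribosomal centring prrB was 0.85, cobO 0.24, ccmB 0.36, atpD 0.15 (probe set 3233) and 0.19 (probe set 4901), sucC 0.11, ihfB 0.15 and xylF 0.37. After control scaling prrB was 1.38, hemN 0.22, cobO 0.77, ccoP 0.12, ccmB 0.90, cbbX 0.43, atpA 0.50, atpD 0.68 (probe set 3233) and 0.73 (probe set 4901), fumC 0.31, gltA 0.42, sucC 0.65, groEL 0.22, appA 0.042, ihfB 0.69 and xylF 0.91. These scalings add 1 amount to every gene of an array, 0.85 for ribosomal centring and 1.39 for control scaling between the groups, which by construction turns falls smaller than that. Control scaling has meaning only if the thrC RNA was added in equal amounts, which is not given in the sources used here. Of all comparisons of the 74 named genes with their alternatives 1480 kept their side of the threshold and, where the gene was called, its direction. In 74 the gene no longer passed, in 29 it turned and in 4 it newly passed. The last were phaC without wild type replicate 1 (0.37), after ribosomal centring (1.12) and after control scaling (1.66), and prrB after cyclic loess (-0.36). Direction was not compared where neither fit called the gene. Low signals limit kdpA and nifD, which had no difference left with a floor at the 10th percentile, and fumC (probe set 4995, -0.06) and flgG (-0.50), whose calls ended with it, as did those of ccmB, ccmD and hypF. A level of prrA, intergenic probe sets and neighbours on the same strand were not run.

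With the replicate number as a block, 339 genes were called, 198 up and 141 down, and the cbb3 list lay at -1.66 with adjusted p = 0.062. Same-numbered arrays did not deviate together (correlations across all tested probe sets of -0.013, -0.0095 and 0.0026), so the numbers were not taken to pair the cultures.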

Other observations

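The tests of ribosomal protein genes, of photosynthesis genes under other scalings and of the unnamed block were chosen after the values they concern, or closely related ones, had been seen, and the gene families below were formed from shared symbol prefixes after seeing the data. Of 16 families with at least 4 genes outside the fixed lists, 1 passed camera: all 4 pqq genes rose (median 2.40, adjusted p = 0.0105, and adjusted p = 0.682 with an estimated correlation). Among families that did not pass, 7 of 8 his genes for histidine synthesis were called as rises (median 0.69, adjusted p = 0.136), as were 4 of 5 cys genes (0.58, adjusted p = 0.445) and 3 of 4 aro genes (0.57, adjusted p = 0.394). Of 10 pur genes for purine synthesis 5 rose (0.30, adjusted p = 0.28). Their directions are those of the deposited scaling.

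Photosynthesis genes had lower signals on the mutant arrays. Over 7 scalings the highest list median, under control scaling, was -3.54 (SE 0.38) for the photosynthetic complexes and -1.85 (SE 0.15) for bacteriochlorophyll. Under that scaling 6 of 6 and 10 of 11 genes were called as falls. This argues against array scaling or a signal-dependent difference as the whole cause for these 2 lists. The SEs take the genes of a list as independent, although the estimated correlation of the complexes was 0.504, so the SE of that list is likely too small. For the 4 carotenoid genes it was -0.67 (SE 0.67) with 1 of them called. Under control scaling an effect of scaling on their level therefore cannot be told apart from a fall, with too few genes to decide. That scaling rests on the untested assumption of equal thrC amounts. Under every other scaling all 4 were called as falls, with medians of -2.40 to -1.21. The lists and their set tests were fixed before the data were examined, while the comparison over scalings, with the bound used to judge it, was chosen afterwards. A hypothesis left open for the first 2 lists is an effect of the genotype. The selection of 3 cultures and the untested identity of the mutation stay open beside it.

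Ribosomal protein genes also had lower signals on the mutant arrays. A trend of change on signal fitted on all other probe sets predicted -0.64 for these 45 genes. The median residual from that trend was -0.21 (SE 0.10), so a signal-dependent difference between the arrays may account for most of the fall. The trend cannot decide this, because its bright end holds other genes that fell, those of the cbb3 oxidase among them. A fall of bright genes with the genotype would leave a like residual. The thrC probe sets bear on a signal-dependent difference too, if they measure an RNA added in equal amounts. Whether they do is not given in the sources used here. They changed by -1.36, further than the brighter 22 of these genes (-1.13). Of the 75 probe sets among the 100 brightest outside the list 70 were lower. But the probe sets numbered 1 to 50, with thrC at 21 to 23, had a median change of -1.29, with 21 falls and 1 rise. Their median signals were dim, at 88.0 in the wild type and 49.3 in the mutant. The thrC change therefore cannot tell a signal-dependent difference apart from a smaller amount of control RNA in the mutant samples. Called rises argue against a common fall of all members with the genotype, since the same 6 members rose under all 7 scalings. Their smallest share, after median centring, was 6 of 42 called members (14.3%, exact 95% interval 5.43% to 28.5%, against a bound of 5% set with these counts already known). That interval takes the members as independent, although their estimated correlation was 0.506, so it decides nothing by itself. The test first used, in which 11 of the 23 dimmer members fell (exact 95% interval 26.8% to 69.4%), had not decided whether all members fell. A fall of part of the members with the genotype stays open.

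The 50 probe sets numbered 5301 to 5350, none of them named here, had higher signals on the mutant arrays: 43 rose and 1 fell, 31 of the 50 lay at least 4-fold higher, and the median signal went from 332 to 2527. The residual from the trend on signal was 2.39 (SE 0.10), which argues against a signal-dependent difference. In 0 of 10000 shuffles of the numbers did a block reach the real median of 2.46 (highest 0.99), which argues against unrelated probe sets. Which RNAs these probe sets measure, and whether genotype or RNA preparation sets their level, stays open, and no biological explanation was tested.

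Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called genes as the real one, which is the real one itself with 342, and the highest of the others gave 0. Every other split puts arrays of both strains into each group, so the difference between the strains adds to its spread. Its 0 calls are therefore no measure of how many calls chance gives. These splits are also too few to reach a share under 0.05.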
